A study of Mus musculus with 19 samples.

How the data were processed

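Messenger RNA of sorted CD4 T cells was measured on 19 one-colour arrays, in 4 populations defined by an IL-2 reporter (GFP) and a Foxp3 reporter (RFP). Per the labels, total RNA was isolated on columns, mRNA-derived cDNA was amplified by a global PCR and labelled with Cy3, and each sample was hybridized to a whole mouse genome array. The scanner values deposited by the authors are linear intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers: background was subtracted and spatial trends removed within each array, with no scaling between arrays. The series table deposited by the authors holds log2 values on a common scale, whose normalization method is not given in the sources used here. Its columns have medians of 3.21 to 3.226 and correlate with the log2 scanner signal at r = 0.949 to 1, and up to 198 cells per array are missing. Groups were taken from the sample titles. The labels speak of 5 replicates per population, and 4 GFP+RFP+ samples were given.

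Each array holds 62976 spots, of which 3671 are controls. The remaining 59305 spots carry 55681 probes. Spots that the software marked as not uniform or as outliers among repeated spots were left out (3296 over all arrays), and repeated spots were averaged. Gene names came from RefSeq accessions in the files for 27235 probes and from the files themselves for 28446. Coordinates are those of the files (mm9). The main analysis used log2 processed signal minus the 75th percentile of the array. Because under 50% of probes were well above background on every array, the percentile was taken over the 6621 probes well above background on all 19 arrays. This set of probes was chosen after the files were read, and the percentile over all probes was run as an alternative. Probes well above background on at least 4 arrays were kept (28065), and for each gene the probe with the highest mean signal was used, which left 20595 genes, 11829 of them with a usual gene symbol.

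Before the data were examined, the comparisons, tests, gene lists, naming rule and most other processing choices to try were fixed. One limma model (limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8) was fitted to all 4 groups with empirical Bayes moderation. Contrasts were Treg against conventional cells with and without the IL-2 reporter, IL-2 reporter-positive against negative cells within each lineage, and the interaction. The remaining pairs of groups were compared by counts only. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Genes named are Foxp3 and Il2, the 6 largest called differences per direction with a usual symbol, and up to 3 members with the smallest p of each list, where lists not called and with fewer than 2 called members could be given by counts. Genes named outside that rule (Gpr83 in the comparisons with the IL-2 reporter, Timm9 and the genes lower in both Treg comparisons) were chosen after their values were seen. The 21 lists were the Treg signature, Treg-repressed genes, suppressive molecules, naive and recirculating T cells, effector-memory, early T cell receptor response, T cell cytokines, IL-2 and STAT5 response, Th1, Th2, Th17, follicular helper T cells, co-inhibition and anergy, cell cycle, type I interferon response, apoptosis regulators, and markers of B cells, myeloid and dendritic cells, NK and CD8 T cells, erythroid cells and platelets, and T cell identity. They were tested with camera at a preset correlation of 0.01, adjusted over 105 tests, and again with an estimated correlation. Properties of whole arrays were compared by exact permutation. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.

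The other processing choices fixed beforehand were normexp background correction with an offset of 50, quantile normalization, median centring, the series table, no filter, a filter for detection on all arrays, the mean of a gene's probes, blocks for replicate number and for slide, fits within each of the 3 slides, a trended robust prior, array weights, a fold threshold of 1 on the log2 scale, only the groups compared, and leaving out each array in turn. Those added after the data were seen were the percentile over all probes, a common floor, the percent of probes detected as a covariate, leaving out the 4 arrays with under 30% of probes detected, the scan day as a block, and detection flags in place of levels.

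The pipeline was tested on simulated data made by resampling the residuals of each gene, with known differences added. Differences of 2, 4 and 8 on the log2 scale were recovered for 10.4%, 49.3% and 69.7% of changed genes in GFP-RFP+ against GFP-RFP- cells, with 9 false calls, and for 4.48%, 43.3% and 74.2% in GFP+RFP+ against GFP+RFP- cells, with 4. For the IL-2 reporter the shares were 11.9%, 41.8% and 75.8% in conventional cells (5 false calls) and 20.9%, 53.7% and 78.8% in Treg (11), and for the interaction 1.49%, 34.3% and 50.0% (3). Lists of 14 genes shifted by -2 had a camera p under 0.05 in 100 of 100 cases, and unshifted lists in 5 of 100. Resampling gene by gene removes correlation between genes and effects shared by a whole array. The simulated rates therefore do not cover these, and do not show how often correlated lists would be called wrongly. The correlation estimated in the data was 0.098 for the Treg-repressed, 0.133 for the interferon, 0.182 for the naive and 0.214 for the erythroid and platelet list. Depth is the share of probes well above background, 21.76% to 44.88% per array, and the number of arrays, 4 or 5 per group, limits the precision.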

Results

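Gene expression was profiled in CD4 T cells from the spleen and lymph nodes of adult female mice on a C57BL/6 background. The mice carried a green reporter of IL-2, the main T cell growth factor, together with a red reporter of Foxp3, the transcription factor that defines regulatory T cells (Treg). The 19 arrays fell into 4 populations by reporter colour: 5 arrays of GFP-RFP- conventional cells, 5 of GFP+RFP- conventional cells with the IL-2 reporter, 5 of GFP-RFP+ Treg and 4 of GFP+RFP+ Treg with the IL-2 reporter (replicates 1, 3, 4 and 5). The title of the series asks how regulatory and IL-2-producing CD4 T cells are related. A tag for cell type in the labels calls all 19 samples conventional, whereas the subtype and source name of the RFP+ samples call them regulatory, and the groups here follow the reporter colours. The labels do not state that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

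The arrays differed in how much signal they carried. The share of probes well above background was 40.7% ± 2.82 (SD, n = 5) on GFP-RFP- arrays, 36.9% ± 4.49 (SD, n = 5) on GFP+RFP-, 32.0% ± 4.91 (SD, n = 4) on GFP+RFP+ and 29.4% ± 6.87 (SD, n = 5) on GFP-RFP+ arrays, with a range of 21.76% to 44.88% over all arrays. GFP-RFP+ arrays had a lower share than GFP-RFP- arrays by an exact permutation test (difference -11.2 points, two-sided p = 0.024, 0.048 after Benjamini-Hochberg over 12 tests). The 75th percentile of signal among the 6621 probes detected on all arrays was 14930 ± 2300 intensity units (SD) on GFP-RFP- arrays, 12770 ± 3010 on GFP+RFP-, 7025 ± 3110 on GFP-RFP+ and 5269 ± 844 on GFP+RFP+ arrays. Both RFP+ populations were dimmer than the RFP- population with the same green colour (exact permutation p = 0.016 each, 0.038 adjusted). Within groups, replicate arrays correlated at a median r across probes of 0.71 in GFP-RFP-, 0.68 in GFP+RFP-, 0.65 in GFP+RFP+ and 0.64 in GFP-RFP+ cells. The number of arrays limits the precision of every value that follows.

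**Figure D1:**
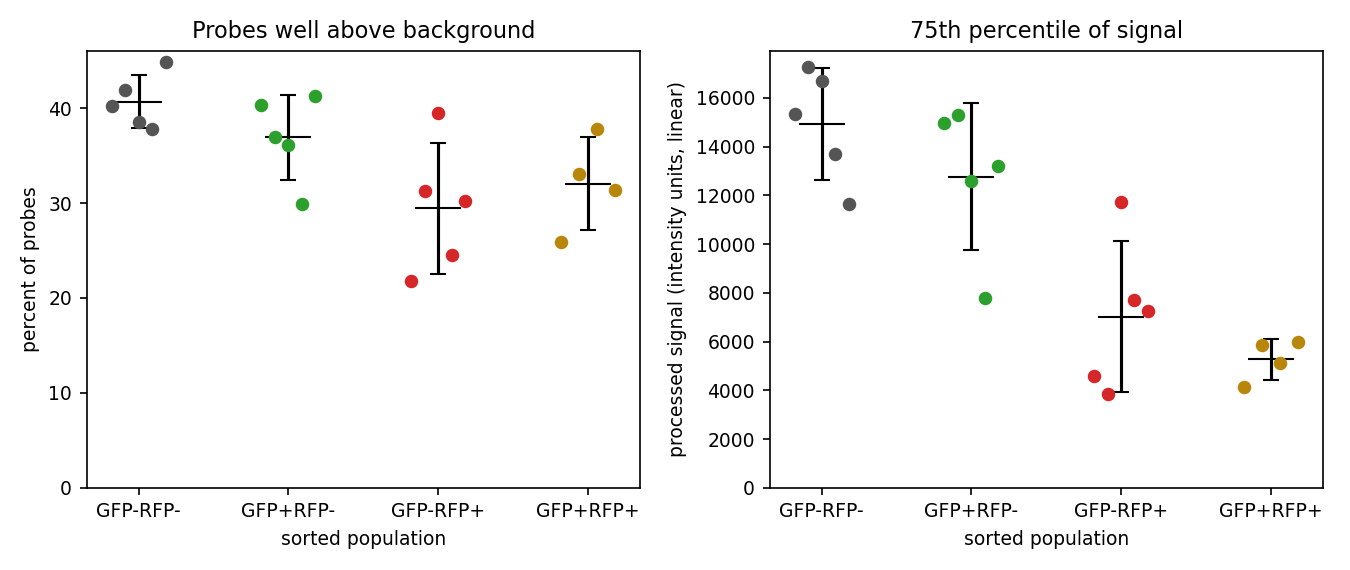
Percent of probes well above background (left) and 75th percentile of processed signal in linear intensity units (right) for each array of the 4 sorted populations, with the group mean and SD as bars. The RFP+ arrays average 29.4% and 32.0% of probes above background, against 40.7% and 36.9% for the RFP- arrays.

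The gene of the red reporter, Foxp3 (1 probe, X:7172301-7172360, mm9), was well above background on all 19 arrays, but at a bright level only on GFP-RFP+ replicate 3. That array gave a log2 signal of 0.25 relative to its 75th percentile. Group means of Foxp3 were -7.89 ± 0.49 (SD, n = 5) in GFP-RFP-, -7.64 ± 0.61 (n = 5) in GFP+RFP-, -5.35 ± 3.32 (n = 5) in GFP-RFP+ and -6.13 ± 0.84 (n = 4) in GFP+RFP+ cells. The Treg difference was 2.54 ± 1.1 (SE) on the log2 scale without the IL-2 reporter (limma, adjusted p = 0.19) and 1.51 ± 1.17 with it (adjusted p = 0.52), so neither passed the test. Foxp3 was called in the first of these under 5 other scalings or background corrections, at log2 differences of 2.39 to 4.50. Those settings called 3466 to 4825 genes in that comparison, 87.1% of them higher with the percentile over all probes. Such a call is therefore not particular to Foxp3. Il2 itself (1 probe, 3:37020012-37020071) was well above background on 2 of 5 GFP-RFP-, 0 of 5 GFP-RFP+, 2 of 5 GFP+RFP- and 1 of 4 GFP+RFP+ arrays. GFP+RFP- cells differed from GFP-RFP- cells by 0.72 ± 1.96 (SE) in log2 Il2 signal. Its mean was -8.47 ± 1.77 (SD, n = 4) in GFP+RFP+ and -10.27 ± 1.07 (n = 5) in GFP-RFP+ cells. Neither difference passed (limma, adjusted p = 1.0 and 0.93). The last 2 means rest mostly or wholly on levels not above background, so no fold is given. The arrays thus gave no measurable Il2 difference that follows the green reporter.

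**Figure D2:**
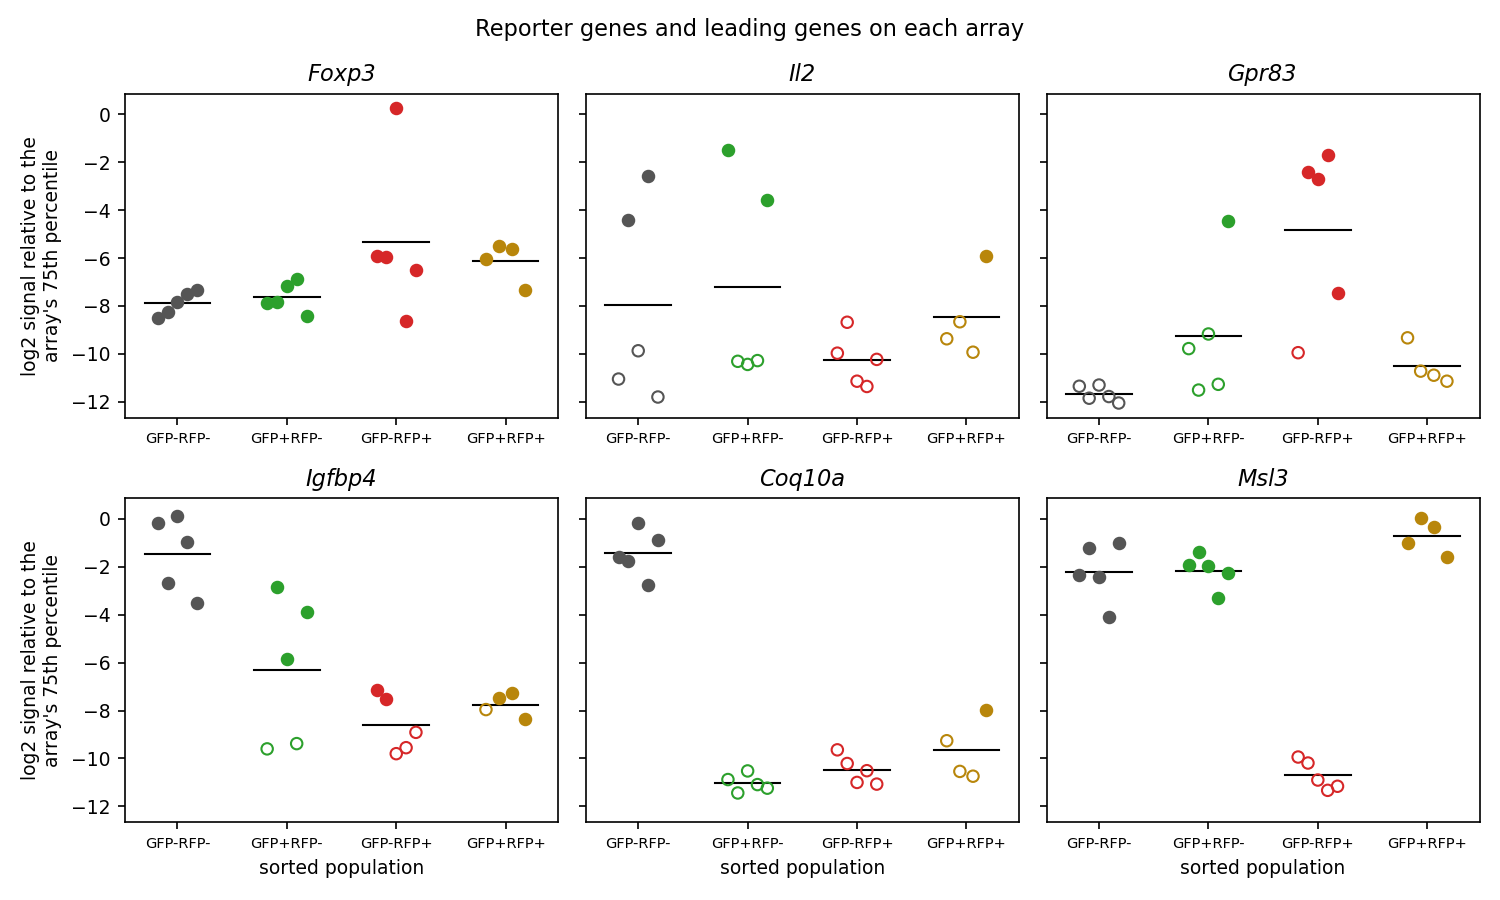
Log2 signal relative to the array's 75th percentile of Foxp3, Il2, Gpr83, Igfbp4, Coq10a and Msl3 on each array of the 4 sorted populations. Filled points are well above background, hollow points are not, and the lines are group means. Foxp3 is bright on a single GFP-RFP+ array at 0.25, and Coq10a and Msl3 are either bright or near background.

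Among cells without the IL-2 reporter, Treg and conventional cells were compared first. In GFP-RFP+ cells, Gpr83, a G protein-coupled receptor enriched on Treg, was above background on 4 of 5 arrays, against 0 of 5 in GFP-RFP- cells. Its group mean, which takes in an array not above background, was at least 27.9-fold above the GFP-RFP- level (limma, adjusted p = 0.033). Il1rl1, the IL-33 receptor chain, rose by 2.23 ± 0.50 (SE) on the log2 scale (adjusted p = 0.038), as did Lgr6, an R-spondin receptor, and Sumf1, a sulfatase-activating enzyme. Igfbp4, a growth factor binding protein typical of naive T cells, fell by 7.14 ± 1.17 (adjusted p = 0.0094), with 2 of 5 GFP-RFP+ arrays above background. The integrin chain Itgb1, annexin Anxa1, the interferon-induced Ifit1 and the B cell receptor component Cd79b also fell. The largest decreases included the splicing factor Sf3b6, the RNA exosome subunit Exosc8, the kinetochore protein Zw10 and the respiratory chain subunit Ndufs8, each well above background on all 5 GFP-RFP- arrays and on no GFP-RFP+ array.

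Of 20595 genes tested, 350 were called in this comparison, 96 higher and 254 lower in GFP-RFP+ cells (limma, adjusted p under 0.05), and 4654 had an unadjusted p under 0.05. Where a gene was above background on no array of the dimmer group, its level there is only bounded, and the difference is given as at least N-fold, from the brighter group's mean over the lowest level well above background on each dimmer array, or over the gene's own value there if that was higher. Log2 differences of such genes, where given for other settings, single slides or the interaction, are fitted against levels near background and serve only to compare settings. Where a gene was above background on some arrays of the dimmer group but not on all, its log2 difference and SE rest in part on such levels too and are fitted values. For Sctr, Pld5, Arl5c and Hmox2 the bound holds for the probe used, since another probe of the gene was above background on some of those arrays. For Gpr83, Lgr6, Sumf1, Sctr, Pld5 and Anxa1 the brighter group was itself not above background on all of its arrays. Their "at least" values therefore hold for the group means and are not strict minimums. Gpr83 was detected on 4 of 5 GFP-RFP+ and 0 of 5 GFP-RFP- arrays, with group means of -4.84 ± 3.66 and -11.67 ± 0.33 (SD, n = 5 each). Lgr6 was at least 10.6-fold higher (means -6.07 ± 1.5 and -10.62 ± 1.07, adjusted p = 0.041), and Sumf1 at least 3.4-fold (adjusted p = 0.0068). Ppy (3.18, adjusted p = 0.037), Sctr (at least 3.58-fold, adjusted p = 0.044) and Pld5 (about 2.62-fold, adjusted p = 0.02) completed the largest increases, and a further probe of Sctr went the other way. Pld5 was above background on 3 of 5 GFP-RFP+ arrays. Among the largest decreases, Sf3b6 was at least 744-fold lower (means -10.40 ± 1.42 against 0.57 ± 0.30, adjusted p = 0.029) and Exosc8 at least 448-fold (means -10.74 ± 0.57 against -0.16 ± 0.35, adjusted p = 0.0029). Zw10 was at least 467-fold lower (adjusted p = 0.0059), Ndufs8 at least 413-fold (adjusted p = 0.026), Adck2 at least 352-fold (adjusted p = 0.03) and Fto, an RNA demethylase, at least 341-fold (adjusted p = 0.016). All such folds are of array signal after a global PCR and do not give transcript amounts per cell. Some of these genes were also missing from conventional arrays: Fto was above background on 2 of 5 and Ndufs8 on 3 of 5 GFP+RFP- arrays, while Exosc8 was on 5 of 5.

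Of the fixed gene lists, the 14 genes that Treg are known to repress were all measured and all lower in GFP-RFP+ cells, with a median log2 difference of -2.63 (camera with a preset correlation, adjusted p = 0.0096 over 105 tests, and adjusted p = 0.55 with an estimated correlation). Igfbp4 was the only member called lower, and 2 members were called when adjusted over the list alone, Igfbp4 and the transcription factor Lef1 (-4.50 ± 1.44 SE, adjusted p = 0.097 over all genes). The naive and recirculating T cell list had 14 of 15 members lower at a median of -2.06 (adjusted p = 0.033, and adjusted p = 0.55 with an estimated correlation), 1 called over all genes and 2 adjusted over the list alone. Its members with the smallest p were again Igfbp4 and Lef1, followed by the actin cross-linker Actn1 (-6.18 ± 2.56, adjusted p = 0.17), since the lists share genes. Type I interferon response genes lay at a median of -4.34, just short of the threshold (adjusted p = 0.05). Of its 12 measured members, Ifit1, above background on 1 of 5 GFP-RFP+ arrays, fell (adjusted p = 0.033), and 7 were called when adjusted over the list alone, among them Xaf1. Of 22 measured Treg signature genes, Gpr83 alone was called, the median was 0.34 and 10 members were lower (adjusted p = 0.5). Tnfrsf9, an activation receptor, lay 0.77 ± 0.32 higher without passing (adjusted p = 0.18). On the log2 scale this was less than the difference in the 75th percentile (7025 against 14930 units), to which signal is relative. In the effector-memory list, Itgb1, above background on 1 of 5 GFP-RFP+ arrays, fell (adjusted p = 0.033) and Anxa1 was at least 13.4-fold lower (adjusted p = 0.045), at a list median of -0.44 (adjusted p = 0.26). The lower lists stood beside the lower share of probes detected on the GFP-RFP+ arrays, and beside lists of other cells. Erythroid and platelet markers had 4 of 4 members lower at a median of -3.09 (camera, adjusted p = 0.24, fry unadjusted p = 0.02), and B cell markers a median of -1.91 (camera, adjusted p = 0.46, fry unadjusted p = 0.046), with Cd79b lower and above background on 2 of 5 GFP-RFP+ arrays (adjusted p = 0.043).

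These counts depended on scaling and on single arrays. With the percentile taken over all probes, 3499 genes were called higher and 517 lower (87.1% higher, against 27.4%), while the median difference over all genes moved from -0.29 to 1.02, and normexp background correction gave 4086 higher and 739 lower. With the percent of probes detected as a covariate, 5 genes were called, all lower. Gpr83 (8.91, against 6.82 without the covariate, limma adjusted p = 0.23) and Igfbp4 (-7.33, against -7.14, adjusted p = 0.24) lost their call. Both values are fitted in part against levels near background. The Treg-repressed list kept its call under the preset correlation at a median of -1.54 (camera, adjusted p = 0.02) and the naive list did not (-1.84, adjusted p = 0.11). Without the covariate both lists lost their call with an estimated correlation (adjusted p = 0.55 each). Without the 4 arrays on which under 30% of probes were detected, 155 genes were called. With the slide as a block, 1231 genes were called, 684 of them higher. Within slide 1, limma called 87 genes, and within slides 2 and 3 it called 0, with 4452 and 3021 genes at an unadjusted p under 0.05. The Treg-repressed list had a median of -2.60 within slide 1 (adjusted p = 0.0099), -1.81 within slide 2 (0.18) and -3.39 within slide 3 (0.52), and the naive list -1.31, -3.35 and -2.68 (0.16, 0.05 and 0.83). Gpr83 differed by 5.01, 9.43 and 7.45 within slides 1, 2 and 3 without a call. Other large increases varied widely over the other settings, single slides included and single arrays left out aside. Log2 differences ranged from 0.13 to 4.98 for Sumf1, 0.08 to 4.83 for Pld5 and 0.35 to 5.03 for Sctr. They ranged from 0.55 to 4.51 for Ppy and 1.12 to 5.86 for Lgr6. Calls of these genes were lost in 5, 5, 10, 6 and 7 of 18 such settings. Leaving out GFP-RFP+ replicate 3 or 4 raised the count to 1148 (304 higher and 844 lower) or 1161 (748 higher and 413 lower, 64.4% higher), and leaving out GFP+RFP- replicate 4 raised it to 567. It fell to 85, 91, 101, 213 and 188 without GFP-RFP- replicates 1 to 5 in turn, and to 123, 109 and 133 without GFP-RFP+ replicates 1, 2 and 5. Calls of Exosc8, Zw10, Fto, Sumf1 and Igfbp4 held without any 1 array, whereas the adjusted p of Gpr83 rose to 0.079 without GFP-RFP+ replicate 2 and that of Il1rl1 to 0.086. The other genes named here also lost their call without 1 or more arrays, with a highest adjusted p of 0.11 for Sctr and 0.1 for Lgr6 (without GFP-RFP+ replicate 1), 0.11 for Cd79b (GFP-RFP+ replicate 2), 0.1 for Anxa1 and 0.062 for Ndufs8 (GFP-RFP- replicate 2), 0.077 for Ifit1 (GFP-RFP+ replicate 1), 0.085 for Ppy, 0.076 for Itgb1, 0.064 for Sf3b6 and 0.062 for Adck2 (GFP-RFP- replicate 1) and 0.051 for Pld5 (GFP-RFP- replicate 2). The naive list lost its call without GFP-RFP+ replicate 2 (adjusted p = 0.1) or 5 (0.086), GFP-RFP- replicate 3 (0.066), 4 (0.058) or 5 (0.054), GFP+RFP- replicate 1 (0.051) or GFP+RFP+ replicate 5 (0.053), and the Treg-repressed list kept its call without any 1 array under the preset correlation, but not with an estimated one on all arrays (adjusted p = 0.55).

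The same comparison among cells with the IL-2 reporter, GFP+RFP+ against GFP+RFP-, asks whether Treg differ from conventional cells when both express it. Genes that fell in GFP+RFP+ cells included Tspan14, a membrane tetraspanin, which was at least 281-fold lower, Pecam1, the adhesion molecule CD31 (at least 211-fold), and Rbmxl1, an RNA-binding protein (at least 154-fold). The respiratory chain subunit Ndufs1 fell to a level above background on 1 of 4 GFP+RFP+ arrays, and the haem-degrading enzyme Hmox2 was at least 582-fold lower. Increases were smaller: Fam178b rose by 2.28 ± 0.40 (SE) on the log2 scale and Pnma2 by 1.89 ± 0.37. Type I interferon response genes had a median difference of -2.22 in GFP+RFP+ cells (adjusted p = 0.029, and adjusted p = 0.55 with an estimated correlation), although within slide 2 it was 0.30. The GFP+RFP+ arrays were also dimmer than the GFP+RFP- arrays, by a difference of -7500 intensity units in the 75th percentile (exact permutation p = 0.016, adjusted 0.038). Because signal is taken relative to that percentile, a dimmer array raises the relative level of any probe whose raw signal is unchanged. The rises of Fam178b and Pnma2 thus include the shift from a mean of 12770 units on GFP+RFP- to 5269 on GFP+RFP+ arrays. On the log2 scale this shift was the larger part of both rises, and of the Foxp3 difference with the IL-2 reporter. Without the IL-2 reporter, the differences of Il1rl1 and Foxp3 include a shift from 14930 on GFP-RFP- to 7025 on GFP-RFP+ arrays. Whether these genes differ beyond the shift was not tested.

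In this comparison 42 of 20595 genes were called, 18 higher and 24 lower (limma), with 3584 at an unadjusted p under 0.05. Group means were -10.38 ± 0.74 (SD, n = 4) against 0.07 ± 0.58 (n = 5) for Hmox2 (limma, adjusted p = 0.04) and -9.24 ± 2.01 against 0.13 ± 0.67 for Ndufs1 (adjusted p = 0.023). They were -3.72 ± 0.32 against -6.0 ± 0.49 for Fam178b (adjusted p = 0.028) and -2.00 ± 0.22 against -3.89 ± 0.34 for Pnma2 (adjusted p = 0.049). Tspan14 had an adjusted p of 0.0059, Pecam1 0.023, Rbmxl1 0.027 and Tmem50a, above background on 1 of 4 GFP+RFP+ arrays, 0.017. Each of these 4 was lower on every GFP+RFP+ array than on every GFP+RFP- array. Of the 12 measured interferon response genes, tested with camera, 11 were lower (adjusted p = 0.029, and adjusted p = 0.55 with an estimated correlation). None was called over all genes, and Ifit1 alone was called when adjusted over the list alone (above background on 1 of 4 GFP+RFP+ arrays, adjusted p = 0.072 over all genes). Of the Treg signature, 2 of 22 members were called when adjusted over the list alone, Swap70 (2.68 ± 0.71) and Tnfrsf9 (1.13 ± 0.34), with a list median of 0.02. Gpr83 was detected on 0 of 4 GFP+RFP+ arrays and 1 of 5 GFP+RFP- arrays. The Treg-repressed list had 11 of 14 members lower at a median of -1.11 (adjusted p = 0.17). The effector-memory list fell just short, at -1.07 (adjusted p = 0.05), with the transcription factor Maf at -4.93 ± 1.03 (adjusted p = 0.058).

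Here the split also moved with the scaling, from 42.9% higher to 94.4% with normexp (4715 higher and 281 lower), 28.0% with quantile normalization (7 and 18), 26.3% with the series table (5 and 14) and 0 higher with median centring or the all-probe percentile (10 lower each). With the slide as a block 127 genes were called, and within each slide limma called 0, with 3079, 1833 and 2853 genes at an unadjusted p under 0.05. The interferon list had medians of -2.07, 0.30 and -6.04 within slides 1, 2 and 3 (adjusted p = 0.17, 0.19 and 0.097), so on slide 2 the median was above 0. Its call was lost without GFP+RFP- replicate 1 (adjusted p = 0.1), GFP+RFP+ replicate 5 (0.082), GFP-RFP- replicate 3 (0.054) or GFP-RFP- replicate 4 (0.058). The count of genes rose to 298 without GFP+RFP- replicate 4 (55.7% higher), 215 without GFP-RFP+ replicate 2 (72.6% higher) and 135 without GFP-RFP+ replicate 4 (63.7% higher). It fell to 2, 13 and 17 without GFP+RFP+ replicates 4, 3 and 1, to 7, 10, 18 and 9 without GFP+RFP- replicates 1, 2, 3 and 5, and to between 18 and 23 without any 1 GFP-RFP- array. Tspan14 was called without any 1 array, and Hmox2 and Pnma2 each lost their call without any of several arrays (highest adjusted p 0.12 and 0.16, GFP+RFP- replicate 5). Without GFP+RFP+ replicate 4 the adjusted p was 0.086 for Ndufs1 and Rbmxl1 and 0.079 for Pecam1 and Tmem50a, and without GFP+RFP- replicate 1 it was 0.1 for Fam178b. Fam178b lost its call in 10 and Pnma2 in 12 of 19 other settings, among them quantile normalization (adjusted p = 0.096 each), the series table (0.1 and 0.11) and median centring (0.15 and 0.18).

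The 2 Treg comparisons share no arrays, but both come from 1 fit with a common estimate of each gene's spread, and in both the RFP+ arrays were dimmer. Called genes overlapped in the same direction in 25 cases, 10 higher and 15 lower in both, against 0.0839 and 0.296 for independent lists of these sizes, and 0 in opposite directions. As the lists are not independent, these expected numbers are a reference only, and the overlap is not a replication. The genes lower in both included Timm9, a mitochondrial import chaperone, whose probe was above background on no RFP+ array (adjusted p = 2.8e-05 without and 6.3e-05 with the IL-2 reporter), together with Tspan14, Ndufs1, Pecam1, Exosc8, Ranbp2, Rnf2 and Jmjd6. Across all genes the differences of the 2 comparisons correlated at r = 0.50, a value across genes, which are not independent replicates. Of the 350 genes called without the IL-2 reporter, 86.9% had the same sign with it. With the percent of probes detected as a covariate the overlap was 1 gene.

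**Figure D3:**
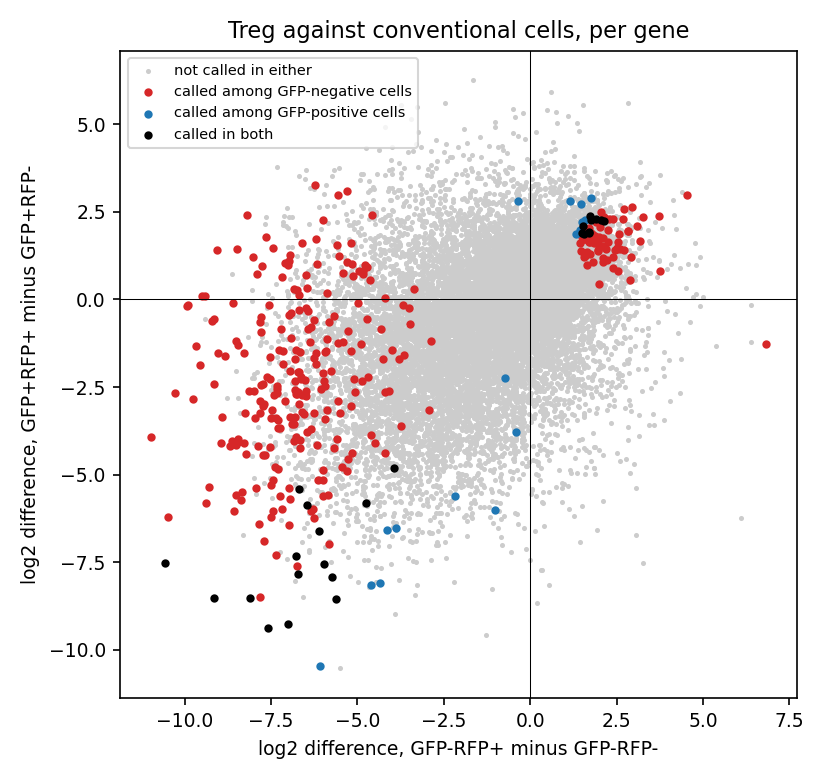
Log2 difference of GFP-RFP+ minus GFP-RFP- cells (horizontal) against GFP+RFP+ minus GFP+RFP- cells (vertical) for each of the 20595 genes. Red points are called in the first comparison, blue in the second and black in both, and the 25 black points lie in the quadrants of shared direction.

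The IL-2 reporter was next compared within each lineage. Between GFP+RFP- and GFP-RFP- conventional cells, Coq10a, a coenzyme Q binding protein, fell to a level not well above background on all 5 GFP+RFP- arrays and was at least 191-fold lower. Arl5c, a small GTPase of the ARF family, was at least 20-fold lower. Genes of naive and recirculating T cells had a median difference of -1.23 and 4 markers of red cells and platelets one of -3.19 in GFP+RFP- cells (adjusted p = 0.029 each, and adjusted p = 0.55 each with an estimated correlation). No gene was called higher.

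These 2 genes were the only ones called of 20595, with 1063 at an unadjusted p under 0.05 (limma). Coq10a means were -11.03 ± 0.35 against -1.43 ± 0.97 (SD, n = 5 each, limma adjusted p = 8.8e-08), and it was called without any 1 array and under every alternative that kept the gene and all slides. Its difference was -9.83, -9.0 and -10.35 within slides 1, 2 and 3 (adjusted p = 0.063, 0.076 and 0.31). Arl5c means were -11.11 ± 0.21 against -4.68 ± 2.19 (adjusted p = 0.02). Another probe of Arl5c had the opposite sign, and its call was lost in 11 of 18 other settings, among them the mean of its probes (-1.84, adjusted p = 0.93), the common floor (-2.51, 0.35), normexp (-3.25, 0.11) and the slide as a block (0.051) and without GFP-RFP- replicate 1 (0.11) or 5 (0.069) or GFP+RFP- replicate 3 (0.051). The naive and recirculating T cell list had 14 of 15 members lower at a median of -1.23 (camera, adjusted p = 0.029, and adjusted p = 0.55 with an estimated correlation). None was called over all genes, and Igfbp4 alone when adjusted over the list alone (-4.86, adjusted p = 0.52 over all genes). The chemokine receptor Ccr7 (-3.59) and the transcription factor Klf2 (-1.89) did not pass. This list mean was -0.96 ± 0.37 (SD, n = 5) in GFP-RFP- and -2.61 ± 1.48 in GFP+RFP- cells. The call was lost without GFP+RFP- replicate 4 (median -0.87, adjusted p = 0.081), GFP+RFP- replicate 1 (0.051), GFP-RFP- replicate 3 (0.066) or GFP-RFP- replicate 4 (0.058) and with the scan day as a block (0.058). Medians within slides 1, 2 and 3 were -0.67, -1.01 and -0.87 (adjusted p = 0.16, 0.2 and 0.74). The 4 measured erythroid and platelet markers, of 9 on the array, had a median of -3.19 (adjusted p = 0.029, and adjusted p = 0.55 with an estimated correlation), with 0 members called on their own. That list was lost without GFP+RFP- replicate 3 (0.13) or 1 (0.067), or GFP-RFP- replicate 3 (0.071), 4 (0.058) or 5 (0.061). Its medians within the slides were -4.33, -1.06 and -2.70 (adjusted p = 0.047, 0.79 and 0.27). The T cell cytokine list had a median of 0.86 (adjusted p = 0.24). The count of genes was 7, 4 and 5 without GFP+RFP- replicates 2, 4 and 5, 1, 10 and 12 without GFP-RFP- replicates 1, 2 and 4, and 4 without GFP+RFP+ replicate 5.

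**Figure D4:**
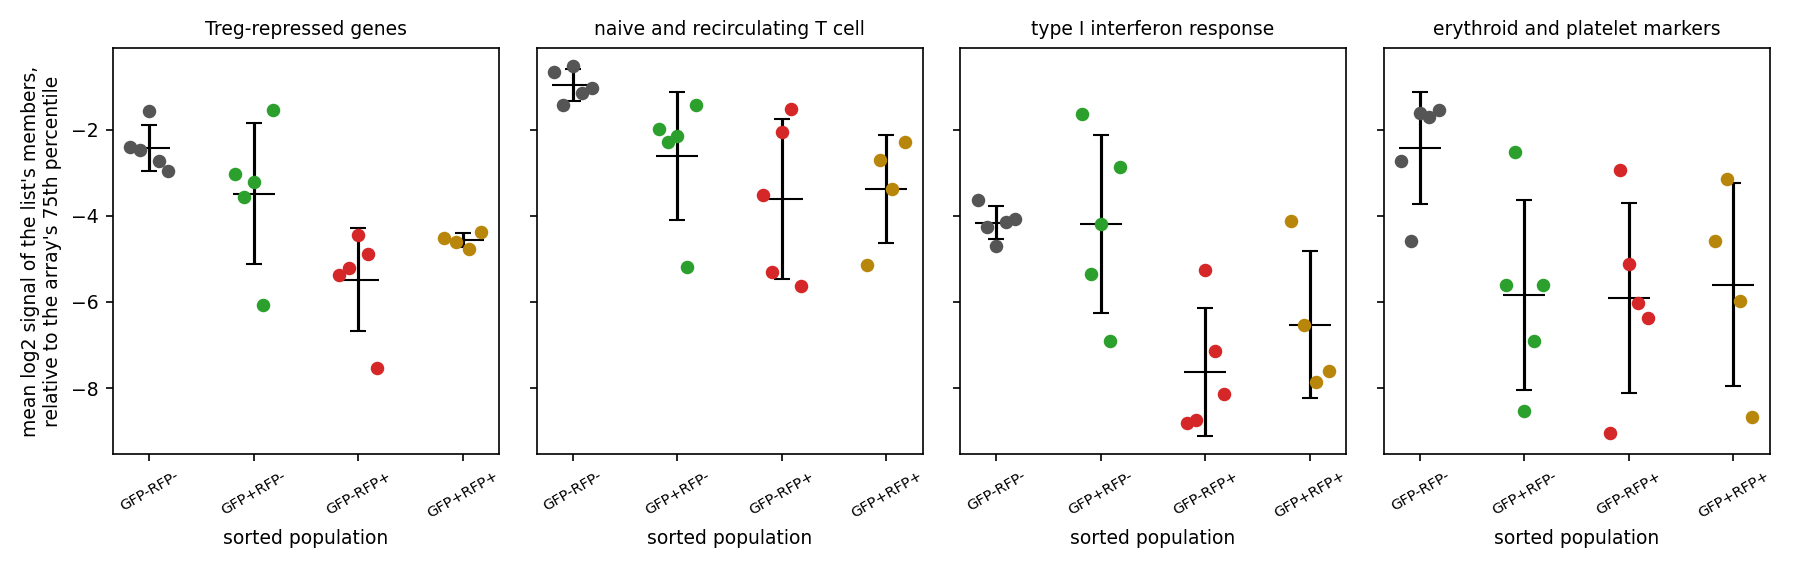
Mean log2 signal, relative to the array's 75th percentile, of the measured members of 4 gene lists on each array of the 4 sorted populations, with group mean and SD. The naive and recirculating T cell list averages -0.96 in GFP-RFP-, -2.61 in GFP+RFP-, -3.61 in GFP-RFP+ and -3.38 in GFP+RFP+ cells.

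Within Treg, GFP+RFP+ against GFP-RFP+ cells differed in Msl3, a chromatin reader, which was at least 301-fold higher in GFP+RFP+ cells. Msl3 was bright on all 4 GFP+RFP+ arrays and not well above background on any GFP-RFP+ array (means -0.74 ± 0.73, SD, n = 4, against -10.71 ± 0.61, n = 5, limma adjusted p = 1.6e-07). It was the only gene called of 20595 (limma, 1114 at an unadjusted p under 0.05), and it was called without any 1 array. Its difference was 9.93, 9.83 and 9.65 within slides 1, 2 and 3 (adjusted p = 0.087, 0.36 and 0.21). Gpr83, above background on none of the 4 GFP+RFP+ arrays, was at least 19.3-fold dimmer there without passing (adjusted p = 0.61). None of the 21 lists was called by camera in this comparison, where Treg signature genes had a median of 0.43 (adjusted p = 0.98) and suppressive molecules 1.24 (adjusted p = 0.65). The count of genes rose to 20 without GFP-RFP+ replicate 3, to 8 and 3 without GFP+RFP- replicates 4 and 3, to 5 without GFP+RFP+ replicate 4, and to between 2 and 6 without GFP-RFP+ replicates 1, 2 and 5, GFP+RFP+ replicate 1 or GFP+RFP- replicate 2. No gene was called in the same direction in both IL-2 reporter comparisons (0 shared, limma), and their differences correlated across genes at r = 0.03.

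The interaction asks whether the IL-2 reporter difference is another one in Treg than in conventional cells. Coq10a and Msl3 were the 2 genes called (limma, 1014 at an unadjusted p under 0.05), but for Coq10a the call does not answer the question. Coq10a (adjusted p = 8.6e-06) was detected on 5 of 5 GFP-RFP-, 0 of 5 GFP+RFP-, 0 of 5 GFP-RFP+ and 1 of 4 GFP+RFP+ arrays, so that it was at least 191-fold lower with the IL-2 reporter among conventional cells, while among Treg it lay near background already without the reporter, where a decrease could not have been seen. Msl3 (adjusted p = 1.3e-05) differed by 0.05 among conventional cells and was at least 301-fold higher with the IL-2 reporter among Treg, being not above background on the GFP-RFP+ arrays only. As those arrays had the lowest mean share of probes detected (29.4%), a loss of Msl3 there was not told apart from a rise with the reporter. With all levels raised to a common floor, which limits the weight of values near background, the interaction was still called for Msl3 (adjusted p = 0.0031). Within slides 1, 2 and 3 the interaction of Msl3 was 9.49, 9.52 and 10.87, none called. Over all other settings in which it was fitted, single arrays left out aside, its adjusted p ranged from 2.4e-06 to 0.41. Foxp3 (-1.04 ± 1.61) and Il2 did not pass, and no list was called, the Treg-repressed genes having a median of 0.96 (adjusted p = 0.22). The count was 13 without GFP-RFP+ replicate 3, and 4 to 6 without GFP+RFP- replicate 2 or 4, GFP+RFP+ replicate 3 or 4, or GFP-RFP- replicate 2 or 4.

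The remaining pairs of populations were compared by counts. GFP-RFP+ Treg against GFP+RFP- conventional cells gave 44 called genes, all lower in Treg (limma, 2671 at an unadjusted p under 0.05). GFP+RFP+ against GFP-RFP- cells gave 1238, of which 911 were higher and 327 lower (73.6% higher), and normexp gave 6205 higher and 594 lower (91.3%). With the all-probe percentile the split was 2507 and 352 (87.7%), with median centring 1873 and 350 (84.3%). With the percent of probes detected as a covariate these counts were 8 and 6. The count of 44 rose to 213 without GFP-RFP+ replicate 3 and 173 without GFP+RFP- replicate 4. It fell to 11, 16 and 11 without GFP+RFP- replicates 1, 3 and 5, to 19, 14 and 20 without GFP-RFP+ replicates 1, 2 and 4, and to 27, 27 and 26 without GFP-RFP- replicates 1 to 3. The count of 1238 rose to 2671 without GFP+RFP+ replicate 5 and to 2041 and 2077 without GFP-RFP+ replicates 2 and 4. It fell to 227, 209 and 175 without GFP+RFP+ replicates 1, 3 and 4, and to 241, 253, 267, 395 and 710 without GFP-RFP- replicates 1 to 5.

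The other lists fixed beforehand were not called in any comparison. The smallest adjusted camera p was 0.17 for early T cell receptor response genes, 0.12 for follicular helper, 0.24 for Th1 and 0.05 for effector-memory genes, all in GFP+RFP+ against GFP+RFP- cells. In that comparison it was also smallest for co-inhibition and anergy (0.62), cell cycle (0.64) and B cell markers (0.4). It was 0.29 for Th2 genes in GFP-RFP+ against GFP-RFP- cells, where Il1rl1 was their only called member of 5 measured. Between GFP+RFP- and GFP-RFP- cells it was 0.22 for the Treg signature, 0.5 for suppressive molecules, 0.34 for IL-2 and STAT5 response genes, 0.65 for Th17 genes and 0.47 for myeloid and dendritic cell markers. Within Treg it was 0.19 for apoptosis regulators and 0.24 for T cell identity genes, and in the interaction 0.19 for T cell cytokines and 0.24 for NK and CD8 T cell markers. Of T cell identity genes, a mean of 100% of members was well above background per GFP-RFP- array, against 86.1% ± 8.43 (SD, n = 5) per GFP-RFP+ array.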

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

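Among the tests below, those of a Treg difference shared with IL-2 reporter-positive cells, the 3 of wrong labels and of a larger memory share were chosen only after the results were seen. For wrong labels on GFP-RFP+ replicates 2 and 5, the limit to these 2 arrays and the condition that GFP-RFP+ replicate 3 has to show the same were also added after the values of that test were seen, and without that condition the test would have argued against wrong labels there.

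Of 76 groups of arrays tested, 5 held an array far apart from the others, against 3.8 expected by chance at 5%. Sf3b6 was 0.88 on GFP+RFP+ replicate 4, against -11.15 to -9.34 on the other GFP+RFP+ arrays. Exosc8 was -0.77 on GFP-RFP- replicate 5 (others -0.14 to 0.10) and -0.53 on GFP+RFP+ replicate 3 (others -10.88 to -9.33). Hmox2 was -1.97 on GFP-RFP- replicate 5, against 0.31 to 1.12. The mean of the naive and recirculating T cell list was -5.20 on GFP+RFP- replicate 4, against -2.28 to -1.44 on the other GFP+RFP- arrays. The interaction was called for Msl3 (9.92, limma adjusted p = 1.3e-05). This value is fitted against levels not above background, so only the lower bound of 301-fold in Treg is a size. Msl3 was missing only on the GFP-RFP+ arrays, which had the lowest mean share of probes detected (29.4%). With percent detected as a covariate it was still called (limma, adjusted p = 8e-05). A loss of the transcript on those arrays was not told apart from a rise with the reporter. Other splits of the arrays called a median of 3 genes for the interaction, against 2 for the real one. Coq10a was called as well (interaction 10.46, adjusted p = 8.6e-06), but it was above background on 0 of 5 GFP-RFP+ arrays, where a decrease with the reporter could not have been seen, so its call does not show a difference between the lineages.

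The 254 genes called lower in GFP-RFP+ than in GFP-RFP- cells had a mean difference of -6.70, on arrays with fewer detected probes. A lower yield of transcripts may account for part of it: the slope of these genes on percent detected within the 9 GFP+ arrays predicted 21.7% of the difference, with an interval of -8.58% to 51.9%, so the test leaves this open. With percent detected as a covariate the median of the set moved from -6.73 to -5.34, and 5 genes in all were called. A Treg difference shared in direction, though not shown to be of the same size, with IL-2 reporter-positive cells is a candidate explanation as well: the set's median in GFP+RFP+ against GFP+RFP- cells was -2.55, and -1.88 with the covariate, below all 10000 random sets of matched level (percentile 0, 95% of them between 0.04 and 0.53). The GFP+RFP+ arrays were also dimmer, so yield and lineage cannot be told apart for these genes.

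Foxp3 was bright on 1 of the 9 RFP+ arrays, GFP-RFP+ replicate 3. Random loss of transcripts when small RNA amounts are amplified may contribute: of 809 genes as bright on that array, 8.03% were dim on all other GFP-RFP+ arrays, within the 0 to 8.69% found over the arrays, which does not decide it. Wrong labels on the other arrays stay open too, as Gpr83 was well above background on 3 of the 4 other GFP-RFP+ arrays, but also on 1 of the 10 RFP- arrays and on 0 GFP+RFP+ arrays. Genes called between other groups argue against them in part: the 254 genes lower in GFP-RFP+ than in GFP-RFP- cells averaged -7.33, -7.39 and -7.23 on GFP+RFP+ replicates 3 to 5, of which 2 lay over 2 SD below the GFP+RFP- mean (-4.64 ± 1.34 SD, lowest -6.78 on replicate 4), and the 327 lower in GFP+RFP+ than in GFP-RFP- cells averaged -7.83 and -7.97 on GFP-RFP+ replicates 2 and 5, where 2 of 2 did (-4.66 ± 1.36 SD, lowest -6.81). It stays open because the latter genes averaged -5.36 on GFP-RFP+ replicate 3 itself, within the GFP+RFP- arrays, and only 1 RFP- array was about as dim; a biological difference between the samples was not tested.

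The naive and recirculating T cell list was lower in GFP+RFP- than in GFP-RFP- cells. With percent detected as a covariate its camera p was 0.001 (0.00059 without) and its median -1.09 (-1.23 without), which argues against a lower yield as the whole cause under the preset correlation. The adjusted p with the covariate was 0.048, close to the threshold, and without the covariate it was 0.55 with an estimated correlation. Without GFP+RFP- replicate 4 the median was -0.87 and the adjusted p 0.081. A larger share of memory-type cells among IL-2 reporter-positive cells may contribute, but the effector-memory list had a camera p of 0.39 and a median of 0.30, which leaves it open.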

How the results depend on the processing

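The results with the percentile over all probes, a common floor, percent detected as a covariate, without the 4 dim arrays and with the scan day as a block come from tests chosen after the results were seen. Below, counts of called genes are given for Treg without the IL-2 reporter (350 in the main setting), Treg with it (42), the reporter in conventional cells (2), the reporter in Treg (1), the interaction (2), GFP-RFP+ against GFP+RFP- (44), GFP+RFP+ against GFP-RFP- (1238) and genes shared by the Treg comparisons (25). Counts not repeated for a setting stayed within 1.5 times. No named gene called in either setting changed its direction, but the called interferon list of Treg with the reporter went from a median of -2.22 to 0.30 within slide 2, uncalled there, and the split of Treg without the reporter turned from 27.4% to 87.1% higher with the percentile over all probes. Genes shared by the IL-2 reporter comparisons numbered 0 in every setting run. Where a count moved and no reason is given, the cause was not tested.

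With normexp the counts were 4825 for Treg without the reporter, 4996 for Treg with it, 5 for the reporter in conventional cells, 7 in Treg, 23 for GFP-RFP+ against GFP+RFP-, 6799 for GFP+RFP+ against GFP-RFP- and 3320 shared. Quantile normalization gave 3466 for Treg without the reporter, 25 with it, 2 for the reporter in Treg, 16 for GFP-RFP+ against GFP+RFP- and 2457 for GFP+RFP+ against GFP-RFP-. Median centring gave, in that order, 3636, 10, 10, 10 and 2223, with 9 shared. The series table gave 3533, 19, 2, 11 and 2694, with 13 shared, and its differences correlated with the main ones at r = 0.945 to 0.984. The percentile over all probes gave 4016, 10, 11, 8 and 2859, with 9 shared. With a common floor the counts were 694, 520, 17 and 25, with 5 for the reporter in conventional cells and 282 shared.

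Without a filter 106 genes were called for Treg with the reporter, 24 for GFP-RFP+ against GFP+RFP-, 5148 for GFP+RFP+ against GFP-RFP- and 50 shared. With detection on all arrays required, fewer genes (5799) were tested and 596 were called for Treg without and 748 with the reporter, 2 for the reporter in Treg, 1 for GFP-RFP+ against GFP+RFP- and 376 shared, while limma called 0 for the reporter in conventional cells and for the interaction (178 and 295 at an unadjusted p under 0.05). The 4 called lists it could test were then not called (adjusted p = 0.48 to 0.61). The mean of a gene's probes gave 6 for the reporter in Treg. A trended robust prior gave 754 and 331 for Treg without and with the reporter, 6 for the reporter in Treg and 214 shared. Array weights gave 1101 and 1699 for Treg without and with it, 9 for the reporter in conventional cells, 72 for GFP-RFP+ against GFP+RFP-, 3871 for GFP+RFP+ against GFP-RFP- and 481 shared. Only the groups compared gave 74 for Treg with the reporter and 3 for the reporter in Treg. Percent detected as a covariate gave 5 and 8 for Treg without and with the reporter, 1 and 3 for the reporter in conventional cells and Treg, 8 for GFP-RFP+ against GFP+RFP-, 6 for GFP+RFP+ against GFP-RFP- and 1 shared. Without the 4 dim arrays the counts were 155 and 189 for Treg, 17 for the reporter in Treg, 4 for the interaction, 737 for GFP+RFP+ against GFP-RFP- and 43 shared.

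With the slide as a block, 1231 and 127 genes were called for Treg without and with the reporter, among them all 350 and all 42 of the main setting, 1 and 2 for the reporter in conventional cells and Treg, 20 for GFP-RFP+ against GFP+RFP-, 2322 for GFP+RFP+ against GFP-RFP- and 95 shared. With the scan day as a block there were 12 for Treg with the reporter, 1 and 3 for the reporter, 21 for GFP-RFP+ against GFP+RFP-, 2005 for GFP+RFP+ against GFP-RFP- and 7 shared. Within slide 1 limma called 87 genes for Treg without the reporter, 15 of them among the 350, and 0 in every other comparison (926 to 4042 at an unadjusted p under 0.05). Within slides 2 and 3 it called 0 in every comparison, with 1494 to 4452 and 1918 to 3672 at an unadjusted p under 0.05, and 0 genes were shared in any slide. Fewer arrays stand behind these fits, and a lone array of a group is assumed to vary like the other groups.

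The replicate block gave 199 and 8 genes for Treg without and with the reporter, 20 for GFP-RFP+ against GFP+RFP-, 645 for GFP+RFP+ against GFP-RFP- and 5 shared, and 13 named genes and 1 list (naive and recirculating, Treg without the reporter, adjusted p = 0.06) were not called with it. Deviations from group means of arrays with the same number correlated at -0.07 to 0.09 in 27 pairs (mean 0.011, against -0.003 for other numbers), and 6 of 19 arrays matched their own number best. This check showed no strong pairing. It cannot exclude that arrays with the same number share a source, which the labels do not state.

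Leaving out each array in turn gave 85 to 1161 genes for Treg without the reporter, 2 to 298 with it, 1 to 12 for the reporter in conventional cells, 1 to 20 in Treg, 2 to 13 for the interaction, 11 to 213 for GFP-RFP+ against GFP+RFP-, 175 to 2671 for GFP+RFP+ against GFP-RFP-, 2 to 136 shared by the Treg comparisons and 0 shared by the IL-2 reporter comparisons. Over all settings, 9568 values of named genes kept their side of the threshold, 335 lost and 154 gained a call, and for lists 3971, 45 and 59. Signal over background limits genes near the detection level, for which a difference can be only a lower bound.

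Other splits of the same arrays, 100 per comparison, were set against the real one, without regard to the slide. A result was held apart from chance if under 5% of splits were as large, with no correction over these tests. This held for the count of Treg without the reporter (1 split as large, the real one, with 350 against at most 181 in another split). The same held for GFP+RFP+ against GFP-RFP- (1 split, 1238, highest other 30). For Treg with the reporter it held only narrowly (4 splits as large, real count 42, highest other 197). As other splits called more genes there, chance is not excluded for that count. By the same permutation of arrays, with the camera p as the measure, it held narrowly for Treg-repressed genes in Treg without the reporter (4 splits as small, real p = 9.1e-05, smallest other 4.2e-05). It held for the naive list in conventional cells (1 split, 0.00059, smallest other 0.0013). Both used the preset correlation, and both lost their call with an estimated one (camera, adjusted p = 0.55 each). It did not hold for the reporter in conventional cells (75 splits, real count 2, highest other 57) or in Treg (88 splits, 1, highest other 1582). Nor did it for the interaction (74 splits, 2, highest other 17) and GFP-RFP+ against GFP+RFP- (5 splits, 44, highest other 826). Nor can it for the naive list in Treg without the reporter (20; 0.0016, smallest other 4.6e-06), erythroid and platelet markers (5; 0.00089, smallest other 2.1e-06) and the interferon list in Treg with it (8; 0.0011, smallest other 3.5e-05). Splits that call several times the real count point to a structure of the samples other than their groups. The highest for the reporter in Treg set GFP+RFP+ replicate 5 and GFP-RFP+ replicates 3, 4 and 5 apart, which are the 3 RFP+ arrays of slide 3 together with GFP-RFP+ replicate 3 of slide 1. These arrays also had the highest 75th percentiles of signal among RFP+ arrays, 5966 to 11720 intensity units, against 3830 to 5860 on the others. A link of this split with that percentile was not tested. With the slide as a block 2 genes were called between the real groups. The highest for Treg with the reporter put GFP+RFP- replicate 4 (29.9% of probes detected) on the side of the GFP+RFP+ arrays. The highest for GFP-RFP+ against GFP+RFP- exchanged GFP-RFP+ replicate 3 (39.51% detected) with GFP+RFP- replicate 4. In both of these splits the 75th percentile of signal parted the sides. It was 4140 to 7786 against 12580 to 15290 intensity units for Treg with the reporter. For GFP-RFP+ against GFP+RFP- it was 3830 to 7786 against 11720 to 15290. The share of probes detected parted the sides only for GFP-RFP+ against GFP+RFP-. For Treg with the reporter, GFP+RFP+ replicate 4 (37.83%) lay above GFP+RFP- replicates 2 (36.97%) and 3 (36.15%). Neither link was tested.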

Other observations

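The counts of detected genes were chosen after the results were seen. Detection flags, which no scaling between arrays changes, gave the genes present on every array of a group and on none of the other. There were 166 such genes in GFP-RFP- against GFP-RFP+ cells and 1 the other way. With the IL-2 reporter, 84 genes were present in GFP+RFP- only and 5 in GFP+RFP+ only. The IL-2 reporter parted fewer: 19 genes present in GFP-RFP- only and 3 in GFP+RFP- only among conventional cells, and 9 in GFP+RFP+ only and 3 in GFP-RFP+ only among Treg. GFP-RFP- cells had 288 such genes against GFP+RFP+ cells, which had 9. The smallest Fisher exact p possible for 1 gene is 0.0079 before correction. On average a gene was detected on 77.4% of GFP-RFP- arrays, 71.6% of GFP+RFP-, 63.2% of GFP+RFP+ and 59.3% of GFP-RFP+ arrays. In each pair given, the group with the higher share had more such genes. No number expected from these shares was computed, so the counts do not show a difference beyond overall detection.

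Among the genes lower in both Treg comparisons, Ndufs1 and Ndufa3, subunits of respiratory complex I, were above background on 3 of 5 GFP-RFP+ arrays each, and on 1 and 3 of 4 GFP+RFP+ arrays. The histone-modifying gene Rnf2, above background on no RFP+ array, was at least 8.55-fold lower without the IL-2 reporter and at least 29.6-fold with it. The nuclear pore gene Ranbp2, the mitochondrial tRNA methyltransferase component Trmt10c and Pecam1 were above background on 1 of 5 GFP-RFP+ arrays each and on no GFP+RFP+ array, and with the IL-2 reporter they were at least 118-fold, 84.7-fold and 211-fold lower.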
